A study of Anguilla anguilla with 66 samples.

How the data were processed

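Liver RNA of 66 European eels (Anguilla anguilla) was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 eel per array. Per the labels, 84 eels were distributed at random over 4 aquaria, 21 in each. One aquarium held mercury at 100 µg/L, 1 held β-sitosterol at 150 µg/L with 0.01% ethanol as vehicle, 1 held ethanol alone and 1 held untreated water. At each of T1 (3 days), T2 (6 days) and T3 (9 days) 7 eels were sampled per aquarium. Arrays exist for 6 eels per time in the sitosterol and ethanol groups and for 5 eels per time in the mercury and water groups.

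Each treatment had a single aquarium, so treatment and aquarium cannot be told apart, and every p-value below measures the spread between eels, not between aquaria. The chemical form of the mercury is not given beyond the metal's name. The labels' wording on RNA integrity numbers leaves unclear which side of 8 was left out. The titles of 12 arrays of the sitosterol experiment, 6 per group, say T3 while their time labels say 6 days. These arrays were grouped as T3 by title, and counting them as T2 was tried as an alternative.

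Per the file headers, the intensity values came from Agilent Feature Extraction 10.7.3.1, which subtracted a spatially fitted background, removed a multiplicative trend within each array and replaced low values by a surrogate. Per the file headers, no step between arrays was applied to these intensities. The deposited series table holds log2 values for 45543 probes, and neither labels nor headers state how it was normalised. Each of its 66 columns correlated best with the array of the same eel, at r between 0.829 and 0.952 across probes, which are not independent replicates. Its column medians ran from -0.15 to 0.09. No pair of arrays held identical values, and the highest correlation between 2 arrays was 0.971 against a median of 0.951.

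Computations used R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8), with figures drawn in matplotlib 3.10.9. The processed signal was log2-transformed, and each array's 75th percentile over non-control probes was set to 0. Spots that Feature Extraction marked as outliers, between 3 and 570 per array, were left out, and the remaining spots of 1 probe were averaged. Probes well above background on at least 5 arrays of an experiment were tested. Group means were fitted with limma's lmFit over all arrays of an experiment (36 for sitosterol, 30 for mercury, and 33 controls for ethanol against water), followed by its moderated test. Adjusted p-values are Benjamini-Hochberg values over the probes tested, called below 0.05. The contrasts were treated minus control at each time, their average over the 3 times, limma's F test of whether the effect differed between times, and ethanol minus water eels averaged over times. Values per gene are log2 differences ± SE.

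The array carries 61377 non-control probes with 43466 distinct sequences. Of these, 10266 carry names of 3422 EeelBase contigs, 196 carry names of 98 protein entries, and 50915 carry only assembly or read identifiers. The names of EeelBase contigs are truncated in the files, so a shortened name may stand for several related proteins. None of the identifiers occurs in the gene table supplied for assembly fAngAng1.pri: 0 of the 98 protein entries matched it. No genome coordinates are given for that reason.

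Before the data were examined, the design, the alternatives and 32 gene lists were fixed. The rule for named genes took 1 probe per gene, the one with the highest mean signal. It named the 12 largest rises and 12 largest falls past the threshold for an averaged contrast, and the 6 largest of each for a contrast at 1 time and for ethanol against water. Where fewer than 3 passed it named the 3 rises and 3 falls with the smallest p, and for each F test the 6 smallest p. Up to 4 members per gene list were added. Metallothionein, HMOX1, vitellogenin, oestrogen receptor alpha, CYP7A1 and CYP1A were to be named in any case, but no probe is named CYP7A1. A gene at background on all arrays of 1 group is given only a bound on its fold.

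Of the 32 lists, 24 had at least 3 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it. The lists of metal binding, bile acid and sterol transport, selenoprotein, mitochondrially encoded, hepatocyte, exocrine pancreas, endothelial and intestine genes had fewer and were not tested. List p-values are Benjamini-Hochberg values over the 24 lists of a contrast, of which 1 is not reported. Counts of members are given over all probes tested and adjusted over the list alone.

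The steps were tested on simulated data made from the real probes' means and spreads with 200 changed probes. For the mercury effect averaged over times, 41 of 67 probes changed 2-fold and 63 of 66 changed 4-fold were recovered among 41358 probes, with 2 false calls. For the sitosterol effect averaged over times these were 51 of 67 and 60 of 66 among 38895 probes, with 5 false calls. For the mercury effect at T1, 18 of 67 and 43 of 66 were recovered, with 3 false calls. For ethanol against water, 45 of 67 and 60 of 66 were recovered among 40501 probes, with 5 false calls. The simulated noise was drawn independently for each probe, without slide or row effects. The false calls therefore do not give the error rate of the real arrays. Random splits of the real arrays, described below, called up to 3, 267, 323 and 151 probes in these comparisons, in the same order.

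The alternatives were normexp background correction (offset 50), quantile normalization, the deposited series table, no filter on dim probes, a filter requiring every array, the slide as a block, the slide with the array's row on it, other sets of arrays in the fit, array weights, and leaving out each array in turn. Chosen only after seeing the data were averaging probes of identical sequence, leaving out slide 10 or the sitosterol array on slide 9, the level of the mucin gene muc2 as a covariate, and, for the gene lists, normexp, the deposited table and the slide with the row. Counts of probes called were also compared with those of 100 splits of the arrays, drawn at random within times. No measured array or per-sample column was left out.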

Results

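Liver transcripts were measured in 66 eels on 66 arrays, in 12 groups formed by 4 treatments and 3 times. The mercury and water groups had 5 eels at each time, and the sitosterol and ethanol groups had 6. The 75th percentile of the array signal lay between 194 and 637 intensity units, and between 45.6% and 69.3% of probes lay well above background. No spot was saturated. The number of arrays limits the precision of every value below. Arrays of the sitosterol experiment were on slides 1 to 5, scanned on day 1, except for 1 sitosterol T3 array on slide 9. Arrays of the mercury experiment were on slides 6 to 10, scanned on days 2 and 3. On slides 6, 7 and 8 all mercury eels were in row 2 of the slide and all water eels in row 1.

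The level of muc2, a gel-forming mucin of mucus-secreting epithelia, varied widely between eels of the same group. It ranged from -7.35 to 6.43 on the log2 scale and was well above background on 44 of 66 arrays. Its median was 6.12 in the water T1 eels, with 5 of 5 above background, and -5.38 in the mercury T1 eels, with 2 of 5. The difference at T1 was -7.81 ± 2.75 (n = 5 and 5) and did not pass (limma adjusted p = 0.149). A contig of claudin 4, a tight junction protein of epithelia, differed in the same direction at T1, by -4.93 ± 1.67 (limma adjusted p = 0.132).

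**Figure D1:**
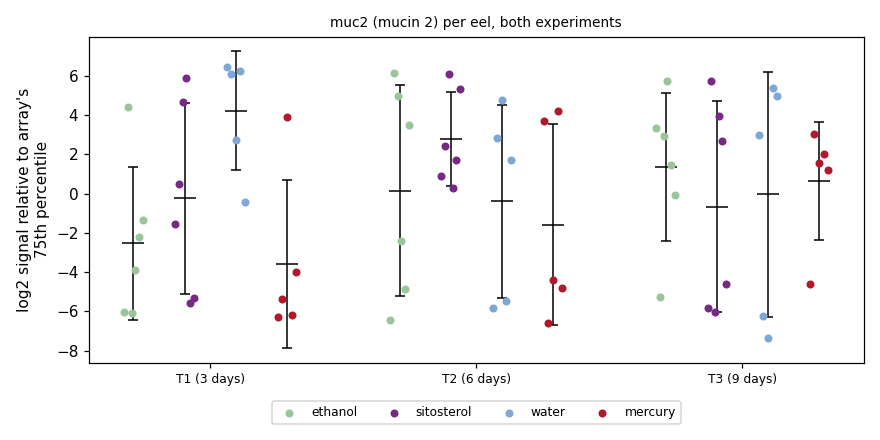
Each point is 1 eel and the vertical axis is the log2 signal of muc2 relative to the 75th percentile of its array. Bars are the mean and SD of 5 or 6 eels. The values run from -7.35 to 6.43, and the water T1 eels have the highest group median, 6.12.

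The mercury comparison asked how the liver transcripts of eels in water with mercury differed from those in clean water. Averaged over the 3 times, a few antioxidant and complement genes passed the threshold, 2 of 38 antioxidant and 3 of 10 complement members. A contig of thioredoxin, a small protein that reduces disulphides, rose by 2.15 ± 0.43 and was above the water mean in 14 of 15 mercury eels (limma adjusted p = 0.0188). A glutathione peroxidase entry (name truncated), of a family that reduces peroxides with glutathione, rose by 1.87 ± 0.39 in 13 of 15 eels (limma adjusted p = 0.024). Complement factor B, part of the alternative complement pathway, rose by 0.94 ± 0.16 in 1 contig (14 of 15 eels, limma adjusted p = 0.00779) and by 0.80 ± 0.16 in another (12 of 15 eels, limma adjusted p = 0.024). Complement C3-H1, a form of the central complement protein C3, rose by 0.76 ± 0.15 in 14 of 15 eels (limma adjusted p = 0.0229). Selenoprotein 1 fell by 0.97 ± 0.14, with 2 of 15 mercury eels above the water mean (limma adjusted p = 0.00223). A glutamine synthetase contig, named for the enzyme that joins ammonia to glutamate, fell by 1.54 ± 0.33, and 0 of 15 mercury eels were above the water mean (limma adjusted p = 0.0321). Thioredoxin, glutathione peroxidase, both complement factor B contigs, complement C3-H1 and selenoprotein 1 stayed called in each of the 30 fits that left out 1 array, and glutamine synthetase in 21 of them. On the 4 slides that held both treatments at the same times these genes differed in the same direction on 4. The genes were chosen on these same arrays, so this is not an independent test. On slides 6, 7 and 8 it also cannot separate mercury from the row. With slide and array row in the fit none of these genes passed, and thioredoxin was at 1.28, glutathione peroxidase at 1.07, glutamine synthetase at -0.71 and selenoprotein 1 at -1.12.

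In total 252 of 41549 probes were called, 173 higher and 79 lower, for 119 distinct targets of which 25 have a name. The lowest adjusted p, 5.1e-06, belonged to the unnamed isotig07627, which fell by 1.16. The other named rises were a cytochrome c oxidase entry (1.23 ± 0.29), v-fos, an immediate early transcription factor (1.02 ± 0.24), an entry named trafficking protein (0.75 ± 0.14, higher in 15 of 15 eels), an entry named deoxyribonuclease (0.69 ± 0.17) and an ADP-ribosylation entry (0.67 ± 0.16). Their limma adjusted p-values lay between 0.0143 and 0.0487. The other named falls were a Krüppel-like factor (-1.90 ± 0.42), a 3-oxo-5-alpha-steroid entry (-1.40 ± 0.32) and the unc-51-like kinase (-1.09 ± 0.25), with limma adjusted p-values of 0.0344, 0.0423 and 0.0414. Under normexp the v-fos call ended (0.22, limma adjusted p = 0.193), and the trafficking, 3-oxo-5-alpha-steroid and unc-51-like entries stayed called at 0.41, -0.63 and -0.51. These 8 further genes were called in 8 to 30 of the 30 fits that left out 1 array. The 3-oxo-5-alpha-steroid entry rests on 1 probe and reversed to 0.79 when slide and array row were in the fit. With the slide as a block 137 probes were called. With slide and array row limma called 0, with 1938 at an unadjusted p under 0.05. By chance 2077 would be expected, and the fit without slide and row had 6758. The fit with slide and row separates row from mercury only through the slides with mixed rows. Without slide 10 the count was 337, 195 higher and 142 lower. Leaving out 1 array moved it to between 104 (without mercury T3 eel 66) and 480 (without mercury T1 eel 3), by more than 1.5 times for 18 of 30 arrays.

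**Figure D2:**
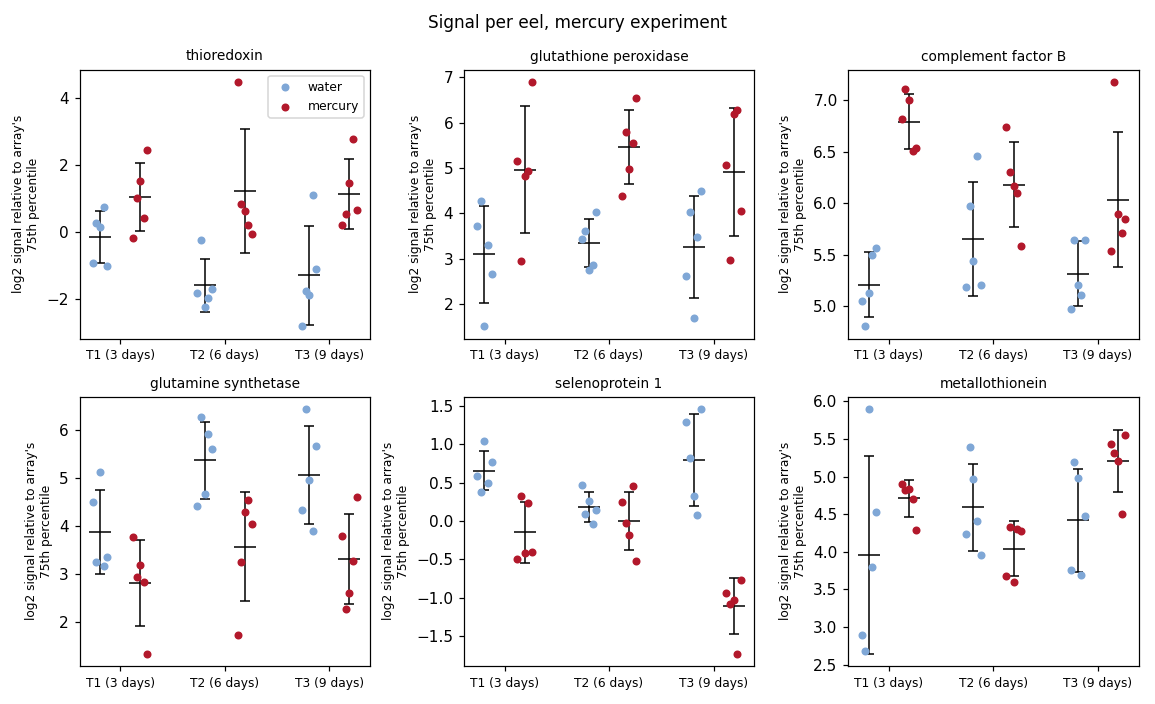
Each point is 1 eel of the mercury experiment (5 per group and time), and the vertical axes are log2 signal relative to the 75th percentile of the array. Bars are the mean and SD. Averaged over times, thioredoxin was 2.15 higher and selenoprotein 1 was 0.97 ± 0.14 lower, and metallothionein differed by 0.33 ± 0.25.

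Among the antioxidant genes of the glutathione and thioredoxin systems, 28 of 38 measured members lay higher in mercury eels and 10 lower. Of these, 2 passed over all probes and 9 rose when adjusted over the list alone (camera adjusted p = 4.5e-04). That call was lost, with adjusted p = 0.32 with an estimated correlation. A further thioredoxin contig was 0.55 ± 0.14 higher, in 15 of 15 eels, peroxiredoxin 1, a peroxide-reducing enzyme, was 0.85 ± 0.22 higher, and the Pi-class glutathione S-transferase, a detoxifying enzyme, was 0.89 ± 0.23 higher. Their limma adjusted p-values over all probes were 0.0541, 0.0565 and 0.0655. The Pi-class transferase was at -0.22 with slide and row in the fit.

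Of 16 heat shock and ER stress genes 11 lay higher, 0 passed over all probes and 5 rose when adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.32 with an estimated correlation). Calreticulin, a calcium-binding chaperone, was 1.00 ± 0.25 and 0.89 ± 0.24 higher in its 2 contigs, and protein disulphide isomerase, which forms disulphide bonds, was 1.00 ± 0.26 and 1.44 ± 0.44 higher. Of 42 proteasome subunits 40 lay higher, with a median of 0.27, 0 past the threshold over all probes and 1 that rose when adjusted over the list alone (camera adjusted p = 6.1e-08; adjusted p = 0.32 with an estimated correlation).

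Of 10 complement and acute phase genes 7 lay higher and 3 passed, both over all probes and adjusted over the list alone (camera adjusted p = 0.010; adjusted p = 0.32 with an estimated correlation). Of 22 interferon and antiviral genes 15 lay higher, with a median of 0.55, and 0 passed over all probes or adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.75 with an estimated correlation). The interferon call ended under normexp (adjusted p = 0.12), quantile normalization (0.067) and the slide as a block (0.061). The heat shock call ended under quantile normalization (0.057), the slide as a block (0.085) and the mean over a gene's probes (0.054), and the complement call under the last of these (0.12).

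Genes of amino acid and nitrogen metabolism lay lower in 5 of 7 members, with a median of -1.11, but 4 of these 5 are contigs of glutamine synthetase, so the list rests largely on 1 gene name. Adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0066; adjusted p = 0.32 with an estimated correlation). The other 3 contigs of glutamine synthetase differed by -1.37 ± 0.33, -1.11 ± 0.31 and -1.97 ± 0.60. The last of them was at 1.27 with slide and row in the fit. Lymphocyte markers lay lower in 11 of 12 members, and 9 fell when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.39 with an estimated correlation). The immunoglobulin mu heavy chain, the antibody chain of IgM, differed by -0.93 ± 0.36, and 1 of 15 mercury eels was above the water mean. Other members are further immunoglobulin heavy chain entries, at -0.91, -0.95 and -0.89, so the members are not independent markers. Stellate cell and fibroblast markers lay lower in 7 of 8 members (camera adjusted p = 0.0097; adjusted p = 0.32 with an estimated correlation). Smooth muscle actin (an alpha smooth aorta contig) differed by -1.35 ± 0.44 there, and by 0.01 with slide and row in the fit. Cytosolic ribosomal proteins lay lower in 72 of 85 members with a median of -0.13 (camera adjusted p = 1.4e-04; adjusted p = 0.75 with an estimated correlation), and with slide and row in the fit their median was 0.41, in the other direction (camera adjusted p = 3.0e-11). These lists were fitted on arrays on which muc2 averaged -2.77 ± 1.59 in mercury against water eels, and each of the 9 lists stayed called with muc2 as a covariate, whereas 2 of 24 lists were called with slide and row in the fit. On the 4 slides with both treatments at the same times, the medians of the amino acid and lymphocyte lists were lower in mercury eels on 4, that of the stellate list on 3 and that of the ribosomal list on 2. The heat shock and proteasome lists were higher on 4 of these slides, and the complement, interferon and antioxidant lists on 3. Slide 10 held a mercury T1 eel and a water T3 eel and is not counted. The lists were called on these same arrays, so the counts of slides are not an independent test. On slides 6, 7 and 8 they also cannot separate mercury from the row.

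The classic metal and dioxin response genes did not pass. Metallothionein, a cysteine-rich metal-binding protein, differed by 0.33 ± 0.25 (limma adjusted p = 0.524), with 0.75 at T1, -0.55 at T2 and 0.78 at T3. Metallothionein 1 differed by 0.23 ± 0.19, heme oxygenase 1, which breaks down heme, by -0.66 ± 0.26, and CYP1A, a cytochrome P450 induced by dioxins, by -0.44 ± 0.20, with limma adjusted p-values of 0.578, 0.209 and 0.259. CYP1A1 differed by -0.38 ± 0.19 and CYP1A9 by -0.67 ± 0.32. Oestrogen receptor alpha differed by 0.17 ± 0.41 (limma adjusted p = 0.871), with -0.16 when muc2 was a covariate. No vitellogenin probe was well above background on 5 arrays, so this egg yolk precursor was not tested.

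Of the other lists, xenobiotic metabolism lay higher in 18 of 31 members (camera adjusted p = 0.63), mitochondrial respiration in 63 of 97 (0.45), alcohol metabolism in 3 of 3 (0.80), inflammation in 9 of 16 (0.54) and erythrocyte markers in 4 of 4 (0.27). Fatty acid oxidation lay lower in 11 of 16 (0.13), glucose and growth genes in 9 of 9 (0.13), muscle markers in 7 of 8 (0.079), bile duct markers in 6 of 10 (0.91), cell cycle genes in 3 of 4 (0.70) and cholesterol synthesis in 3 of 5 (0.80). Fatty acid synthesis was lower in 2 of 4 (0.80), macrophage and granulocyte markers in 2 of 4 (0.50) and oestrogen-responsive liver genes in 2 of 3 (0.46).

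At T1, after 3 days, 388 probes were called, 273 higher and 115 lower, for 180 targets of which 38 have a name. With muc2 as a covariate 275 were called, 220 higher and 55 lower. With the slide as a block 65 were called, 57 higher and 8 lower. With slide and row limma called 0, with 2107 at an unadjusted p under 0.05 where 2077 would be expected by chance. Leaving out 1 array gave between 61 (without water T1 eel 25) and 987 (without mercury T1 eel 3). Without water T1 eel 50 it gave 980, 448 higher and 532 lower, so the excess of rises did not hold there. Complement factor B rose by 1.71 ± 0.29 and 1.59 ± 0.28 in its 2 contigs and complement C3-H1 by 1.46 ± 0.27, each in 5 of 5 mercury eels (limma adjusted p of 0.0116, 0.0116 and 0.0123). Calreticulin rose by 2.03 ± 0.44 and 1.85 ± 0.42, the cytochrome c oxidase entry by 2.26 ± 0.50, v-fos by 1.85 ± 0.42 and a germinal histone entry by 1.61 ± 0.38, with limma adjusted p-values between 0.0316 and 0.0422. Under normexp the calls of v-fos (0.34, limma adjusted p = 0.288) and the germinal histone (0.84, limma adjusted p = 0.0543) ended. An anterior gradient entry, named for a family of secretory pathway proteins, fell by 2.78 ± 0.60 (1.10 under normexp), a eukaryotic translation entry by 1.02 ± 0.25 and AHNAK by 0.76 ± 0.17. Ataxin 2-binding protein, at background in the mercury T1 eels, was at least 1.42-fold lower and rests on 1 probe, and its call ended under normexp (limma adjusted p = 0.187). Lymphocyte markers lay lower in 12 of 12 members, and 9 fell when adjusted over the list alone (camera adjusted p = 8.1e-07; adjusted p = 0.39 with an estimated correlation). An immunoglobulin heavy chain entry differed by -1.96 ± 0.66, and several of the lymphocyte members are entries of that chain. Muscle markers lay lower as a list (camera adjusted p = 0.0125; adjusted p = 0.39 with an estimated correlation), but not with muc2 as a covariate (camera adjusted p = 0.32). A myosin regulatory entry differed by -4.34 ± 1.44 in the same eels in which muc2 differed by -7.81. The complement list was higher (camera adjusted p = 0.0499; adjusted p = 0.39 with an estimated correlation) and was not called under quantile normalization (camera adjusted p = 0.054), the deposited values or the slide as a block. With the deposited values the muscle list was not called either. With slide and row 2 lists were called at T1, 2 higher and 0 lower, so the lymphocyte and muscle calls ended there. Without slide 10, which held 1 mercury T1 eel, 146 probes were called, and with only the 2 groups in the fit limma called 0, with 5798 at an unadjusted p under 0.05.

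At T2, after 6 days, limma called 0 probes, with 6421 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0985. Without mercury T2 eel 35 it called 89, and without mercury T2 eel 58 it called 92. The named genes with the smallest p did not pass: a eukaryotic translation entry (0.73 ± 0.15), the mki67 FHA domain entry (1.48 ± 0.33), an adenosylmethionine entry (at background in 1 group and of the opposite sign, -0.03, under normexp), the unc-51-like kinase (-1.92 ± 0.44), a glycine N-acyltransferase entry (-1.47 ± 0.35) and a ubiquitin-conjugating entry (-1.09 ± 0.27). Proteasome subunits lay higher (camera adjusted p = 9.7e-07), ribosomal proteins lower (1.6e-09, in the other direction with slide and row in the fit), amino acid genes lower (0.023, and 0.0503 under normexp) and complement genes higher (0.026). Each call was lost, at adjusted p = 0.64 with an estimated correlation.

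At T3, after 9 days, 7 probes were called, 7 of them lower, 5 for isotig07627 and 2 for selenoprotein 1. Selenoprotein 1 fell by 1.91 ± 0.25, with 0 of 5 mercury eels above the water mean (limma adjusted p = 2.2e-04). Under normexp 8 probes were called, 1 higher and 7 lower, with only the 2 groups in the fit 2, and with array weights 31, 17 higher and 14 lower. With slide and row limma called 0, with 2305 at an unadjusted p under 0.05 where 2077 would be expected by chance. The selenoprotein 1 call ended in that fit and with only the 2 groups in the fit. The antioxidant list was higher in 31 of 38 members (camera adjusted p = 9.7e-09; adjusted p = 0.063 with an estimated correlation). Its Pi-class glutathione S-transferase was 1.86 ± 0.40 higher and a further glutathione S-transferase 1.43 ± 0.33 higher, each in 5 of 5 eels, without passing over all probes (limma adjusted p of 0.173 and 0.248). The xenobiotic list was higher (camera adjusted p = 0.0020; adjusted p = 0.14 with an estimated correlation), as were the proteasome list (camera adjusted p = 1.9e-05; adjusted p = 0.49 with an estimated correlation) and the interferon list, in 20 of 22 members (camera adjusted p = 5.3e-06; adjusted p = 0.31 with an estimated correlation). The amino acid list was lower (camera adjusted p = 0.011; adjusted p = 0.31 with an estimated correlation), with a glutamine synthetase contig at -2.11 ± 0.53. The stellate list was lower too (camera adjusted p = 0.014; adjusted p = 0.31 with an estimated correlation), but in the other direction with slide and row in the fit. In the inflammation list, which lay lower (camera adjusted p = 0.036; adjusted p = 0.31 with an estimated correlation), collagenase 3, a matrix-degrading protease, differed by -2.84 ± 0.83. That list was not called under normexp, quantile normalization or the deposited values.

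Limma's F test called 0 probes for a mercury effect that differed between times, with 4633 at an unadjusted p under 0.05 and a lowest adjusted p of 0.169. The named genes with the smallest p included a v-fos contig (2.12 at T1, 2.49 at T2 and -1.92 at T3), a proteasome beta entry (-1.16, 1.73 and 1.33), a copine entry (0.65, -1.32 and 1.25) and selenoprotein 1 (-0.80, -0.19 and -1.91). The effects at the 3 times are therefore given side by side and not as different.

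The sitosterol comparison asked how eels given the plant sterol β-sitosterol differed from eels given its ethanol vehicle. Averaged over times limma called 0 of 41140 probes, with 1792 at an unadjusted p under 0.05 where 2057 would be expected by chance, and the lowest adjusted p was 0.649. The unadjusted count depended on the processing. It was 1942 with quantile normalization, 4008 with normexp and 9671 with no filter on dim probes, which tests more probes, each with 0 called. The gene nearest to a difference among the fixed oestrogen-responsive genes was oestrogen receptor alpha, the nuclear receptor through which oestradiol acts in fish liver. It was 0.99 ± 0.25 higher (95% interval 0.49 to 1.49), above the ethanol mean in 16 of 18 eels, but did not pass over all probes (limma adjusted p = 0.978). Adjusted over the list alone its p was 0.0010, in a list of 3 genes, and it is the 1 gene of the list that rose there. It was higher by 0.46 at T1, by 1.88 ± 0.43 at T2, in 6 of 6 eels, and by 0.63 at T3. Under normexp the difference shrank to 0.57 averaged over times and to 1.14 at T2, without passing (limma adjusted p of 0.200 and 0.251). At T2 its limma adjusted p was 0.546. With no filter on dim probes that p was 0.048 at the same difference, in a fit in which 158 of 160 calls were higher and the median of all probes was 0.19. The 2 oestrogen receptor beta entries differed by 0.12 ± 0.12 and 0.08 ± 0.24. Of the 5 slides with both treatments oestrogen receptor alpha was higher in sitosterol eels on 4. On slides 1, 2 and 5 all sitosterol eels were in row 1 and all ethanol eels in row 2. There treatment and row cannot be told apart. On slides 3 and 4, where the treatments shared their rows, it differed by 2.00 and -0.76.

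**Figure D3:**
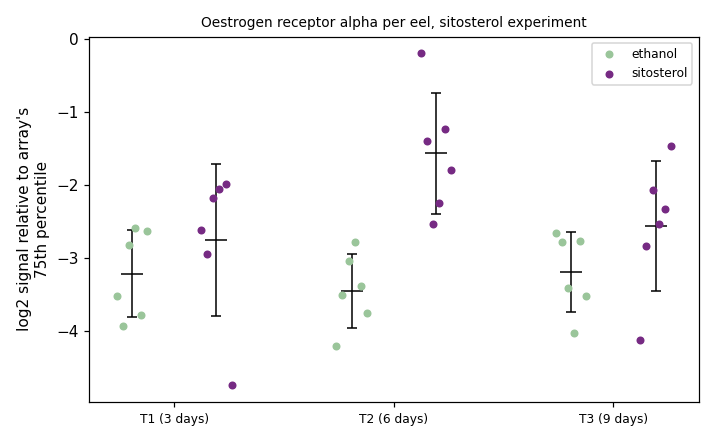
Each point is 1 eel of the sitosterol experiment (6 per group and time), and the vertical axis is log2 signal relative to the 75th percentile of the array. Bars are the mean and SD. At T2 the sitosterol eels were 1.88 higher than the ethanol eels.

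As a list, oestrogen-responsive genes lay higher in 3 of 3 members (camera adjusted p = 0.017; adjusted p = 0.35 with an estimated correlation). These members are oestrogen receptor alpha at 0.99 and the oestrogen receptor beta entries at 0.12 and 0.08. Vitellogenin was not tested, so the list adds little to oestrogen receptor alpha itself. Ribosomal proteins lay higher in 78 of 86 members, with a median of 0.13 (camera adjusted p = 1.5e-09; adjusted p = 0.46 with an estimated correlation), and proteasome subunits lower in 35 of 39, with a median of -0.12 (camera adjusted p = 6.7e-05; adjusted p = 0.54 with an estimated correlation). Fatty acid oxidation genes lay higher in 13 of 16 (camera adjusted p = 0.0033; adjusted p = 0.35 with an estimated correlation). Their lead members were fatty acid binding proteins, carriers of fatty acids in the cytosol, at 0.38 ± 0.18 and 1.10 ± 0.54. Lymphocyte markers lay higher in 13 of 13 (camera adjusted p = 0.0033; adjusted p = 0.54 with an estimated correlation) and erythrocyte markers in 4 of 4 (camera adjusted p = 0.0038; adjusted p = 0.46 with an estimated correlation), among them the hemoglobin alpha chain at 0.74 ± 0.41. The lymphocyte members are not independent, since several are immunoglobulin heavy chain entries, at 0.46, 0.46 and 0.45. Muscle markers lay lower in 8 of 9 (camera adjusted p = 0.0049; adjusted p = 0.35 with an estimated correlation), interferon genes in 15 of 20 (camera adjusted p = 0.017; adjusted p = 0.59 with an estimated correlation) and complement genes in 9 of 10 (camera adjusted p = 0.039; adjusted p = 0.52 with an estimated correlation). Counted over all probes 0 members of these 9 lists passed by limma. Under normexp 7 of 24 lists were called, 4 higher and 3 lower, and with slide and row 7, 4 higher and 3 lower.

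**Figure D4:**
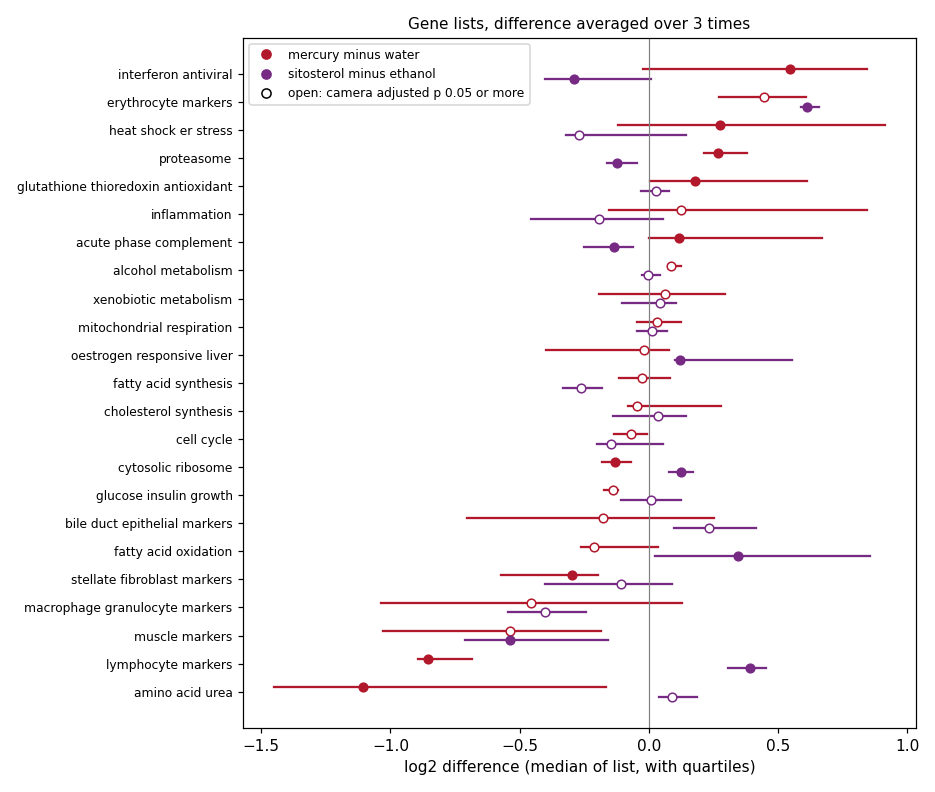
The vertical axis names gene lists tested in both experiments, and the horizontal axis is the log2 difference averaged over 3 times. Circles are the median of the list's genes and lines their quartiles, filled where camera's adjusted p was under 0.05 at the preset correlation. The amino acid list has a median of -1.11 in mercury eels, the proteasome list 0.27 in mercury and -0.12 in sitosterol eels.

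Cholesterol synthesis genes, which sterols regulate, lay higher in 2 of 4 sitosterol members (camera adjusted p = 0.93), and fatty acid synthesis genes lower in 4 of 4 (0.096). Antioxidant genes lay higher in 21 of 38 (0.72), metallothionein differed by 0.48 ± 0.26 and metallothionein 1 by 0.36 ± 0.18. CYP1A differed by 0.15 ± 0.24, CYP1A1 by 0.04 ± 0.26, CYP1A9 by -0.17 ± 0.37 and heme oxygenase 1 by -0.39 ± 0.39, of which CYP1A1 and CYP1A9 flipped sign under normexp. The other named genes with the smallest p averaged over times were an iron/zinc purple acid entry, at background in ethanol eels, an alpha-L tissue entry (-0.43 ± 0.13), a centrosomal entry (-0.50 ± 0.15) and NUP43, a nuclear pore protein (-0.30 ± 0.10).

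Of the other lists in sitosterol eels, xenobiotic metabolism lay higher in 19 of 31 members (camera adjusted p = 0.72), mitochondrial respiration in 55 of 97 (0.72), amino acid genes in 6 of 7 (0.37), glucose and growth genes in 5 of 9 (0.89) and bile duct markers in 6 of 8 (0.058). Heat shock and ER stress genes lay lower in 9 of 14 (0.37), inflammation in 10 of 16 (0.096), stellate markers in 6 of 9 (0.72) and macrophage and granulocyte markers in 4 of 4 (0.10). Alcohol metabolism was split 2 and 2 (0.80), and cell cycle genes lay lower in 3 of 4 with a test pointing up (0.80).

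At each single time limma called 0 probes in sitosterol eels, with 1657 at T1, 2474 at T2 and 1532 at T3 at an unadjusted p under 0.05. With normexp these counts were 1993, 4507 and 1677. Among the named genes with the smallest p at T1 were actinin alpha 2 (1.15 ± 0.37), cyclin D1, a driver of the cell cycle (0.88 ± 0.29), a PPAR-alpha interacting entry (-1.43 ± 0.39) and a mitochondrial ribosomal entry (-0.98 ± 0.31), all at limma adjusted p = 0.999. At T2 they were, beside oestrogen receptor alpha, a gamma-glutamyl entry (at least 2.39-fold higher), gremlin 1, a secreted BMP antagonist (at least 2.09-fold higher), a fatty acid amide entry (-1.04 ± 0.29) and a DNA replication entry (-1.21 ± 0.37), at limma adjusted p = 0.824. Lymphocyte markers were higher at T2, with 9 past the threshold adjusted over the list alone (camera adjusted p = 2.0e-08; adjusted p = 0.80 with an estimated correlation). The immunoglobulin heavy chain entry, of a chain with several entries in this list, was 1.67 ± 0.61 higher in those eels, and muc2 was 2.65 ± 2.45 higher. At T3 the smallest p belonged to an iron/zinc purple acid entry (at least 2.22-fold higher), a zinc CCHC entry (0.65 ± 0.18), NDC80, a kinetochore protein (-2.04 ± 0.62), and creatine kinase-2 (-2.23 ± 0.81). At T1 the antioxidant list was higher and the complement and muscle lists lower (camera adjusted p of 0.032 each; adjusted p = 0.86 with an estimated correlation for each). With the deposited values 0 of these 3 were called. The antioxidant call also ended under normexp, quantile normalization, and slide and row, and the complement call under normexp. At T2 ribosomal proteins were higher (camera adjusted p = 4.5e-04), and proteasome subunits (1.3e-06) and interferon genes (0.014) lower, at adjusted p = 0.81, 0.80 and 0.81 with an estimated correlation. The ribosomal call ended under normexp too (camera adjusted p = 0.47). At T3 the ribosome, respiration, fatty acid oxidation and amino acid lists were higher and the muscle, inflammation, macrophage and interferon lists lower, with camera adjusted p between 1.2e-08 and 0.035. Each of these 8 calls was lost, at adjusted p = 0.45 or more with an estimated correlation, and 3 were made under normexp. The F test across times called 0 probes by limma, with 1878 at an unadjusted p under 0.05.

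The ethanol comparison set the vehicle eels against the water eels, 18 against 15, to show the background between the 2 controls. Of 41491 probes 246 were called, 218 higher and 28 lower in ethanol eels, for 148 targets of which 20 have a name. Otoraplin, a secreted protein first described in the inner ear, was at background in the water eels and at least 2.54-fold higher in ethanol eels, in 15 of 18 (limma adjusted p = 7.6e-08). It rests on 1 probe. Serine peptidase 1 rose by 1.64 ± 0.31 in 17 of 18 eels (limma adjusted p = 0.00445) and a cAMP responsive entry by 1.48 ± 0.26 in 16 of 18 (limma adjusted p = 0.00153). Under normexp both calls ended, at 0.44 and 0.51 (limma adjusted p of 0.102 and 0.0945). Zwilling a was at least 1.65-fold higher and lumican, a proteoglycan of the extracellular matrix, at least 1.19-fold higher. An alanyl-tRNA synthetase entry was called too, but its bound gives no fold. The calls of zwilling a, lumican and this entry ended under normexp too. Ribosomal proteins lay lower in 77 of 85 members (camera adjusted p = 5.3e-08) and proteasome subunits higher (camera adjusted p = 2.7e-04), both at adjusted p = 0.76 with an estimated correlation, and both had the other sign of camera's test with the deposited values. With normexp 81 probes were called, 50 higher and 31 lower, and with the deposited values 1589, 697 higher and 892 lower. The 2 controls shared no slide and no scan day, so slide, scan day, aquarium and ethanol cannot be told apart here, and mercury and sitosterol effects were not compared with each other for the same reason.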

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

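The fit with muc2 as a covariate and the test on vitellogenin were chosen after the results they bear on had been seen. The comparisons with other splits of the samples follow rules set before the data were examined. The flags on single arrays follow such a rule too, but several genes it was applied to were chosen from the mercury results.

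A sample far from the others of its group was found for 16 of 132 combinations of group and quantity, where chance flags about 1 in 20 groups. For the 75th percentile of the signal, ethanol T3 eel 46 had 242 against 376 to 442 in the others, and mercury T2 eel 11 had 490 against 305 to 354. Mercury T2 eel 59 had 46.4% of probes well above background against 58.1% to 62.1%. For thioredoxin the log2 level was -3.27 in ethanol T2 eel 14, -0.26 in water T2 eel 10 and 4.49 in mercury T2 eel 11, where the other mercury T2 eels had -0.07 to 0.83. Complement factor B stood at 7.33 in ethanol T2 eel 13, 6.66 in sitosterol T2 eel 63 and 7.18 in mercury T3 eel 20, and complement C3 at 6.31 in ethanol T2 eel 13. Glutamine synthetase stood at 6.12 in sitosterol T3 eel 71. Oestrogen receptor alpha stood at -4.75 in sitosterol T1 eel 56, -5.13 in water T3 eel 42 and -0.76 in mercury T3 eel 73. Muc2 stood at 3.89 in mercury T1 eel 27, where the others had -6.30 to -3.98, and at -4.61 in mercury T3 eel 19, where they had 1.22 to 3.05.

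For the mercury effect averaged over times, the 252 probes called were set against 100 splits of the arrays. Of these 1, the real one, called as many, and the highest other called 3. This excludes chance only for splits that ignore the slides. With the slide as a block 137 probes were called, and with slide and row 0. At T3 chance can be excluded too (1 of 100, 7 against 3), for splits that ignore the slides. Of the splits 3 of 100, the real one included, called as many lists as the real 9, and the highest other called 10. This share is below the limit set beforehand, at the preset correlation and for splits that ignore the slides. As a random split called more lists than the real one, chance is not excluded for the lists. The other splits called a median of 4 lists. With an estimated correlation 0 lists were called in the real split, and with slide and row 2. At T1 1 of 100 splits, the real one, called as many, 388 against a highest other of 323. These splits ignore the slides, and with the slide as a block 65 probes were called, so at T1 chance is excluded only for splits that ignore the slides. At T2 and for the difference between times limma called 0 in the real split, with 6421 and 4633 probes at an unadjusted p under 0.05. Each of the 100 splits then calls as many, whatever the data, so these comparisons could not exclude chance and decide nothing. The highest others called 8 and 325. The latter points to a structure of the samples, and which one was not tested.

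For the sitosterol effect at T1, T2, T3, averaged over times and between times limma called 0 in the real split, with 1657, 2474, 1532, 1792 and 1878 probes at an unadjusted p under 0.05. Here too 100 of 100 splits call as many whatever the data, so the comparison decides nothing. The highest others called 1020, 4, 17, 267 and 256, which at T1, averaged over times and between times points to a structure of the samples that was not identified. For its 9 lists chance cannot be excluded (10 of 100 splits, highest other 13). For ethanol against water eels chance can be excluded for the 246 probes (1 of 100, highest other 151), only for splits that ignore the slides. For the 2 lists it cannot be excluded (87 of 100, highest other 10).

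The mercury differences were weighed first. The row of the array on the slide was checked on the sitosterol slides with 1 treatment per row. There the called probes differed between rows by 0.0878 of the mercury difference (SE 0.125, 3 slides). On the single slides this was -0.079, 0.010 and 0.331. It argues against a row effect shared by all slides as the whole cause. It cannot decide on a row effect of the mercury slides alone, and row was also sitosterol against ethanol on those slides. RNA of mucin-producing tissue as the main cause for the called probes as a set is argued against by the fit with muc2 as a covariate. In it the called probes had a median difference of 0.875 (median SE of single probes 0.178) against 0.859 without it. This median pools 173 rises and 79 falls, so it cannot decide for the falls alone. With muc2 the called falls averaged over times were 147, but at T1 they went from 115 to 55. A part in the falls at T1 therefore stays open. Errors of single spots are argued against by copies of the same sequence, 145 of 151 of which (96.0%, 95% exact interval 91.6% to 98.5%) moved the same way. The 252 probes hold 197 distinct sequences on the same eels, so this interval treats dependent probes as independent. With slide and row in the fit the median over 241 of the 252 probes was 0.833. The median SE of single probes was 0.459, against 0.167 in the fit without slide and row. Selenoprotein 1 did not shrink in that fit, but thioredoxin shrank to 1.28, glutathione peroxidase to 1.07 and glutamine synthetase to -0.71. The 3-oxo-5-alpha-steroid entry reversed to 0.79. As limma called 0 probes in that fit and its SE was wide, it clears no gene, selenoprotein 1 included. A part played by slide or row is left open for all called probes, most of all for the genes that shrank or reversed. Aquarium and mercury cannot be told apart, since each had 1 aquarium, so a response to mercury may be one reading and a difference between tanks another.

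For ethanol against water eels, errors of single spots are argued against by copies of the same sequence, 125 of 134 of which (93.3%, 95% exact interval 87.6% to 96.9%) moved the same way. The called probes hold 203 distinct sequences on the same eels, so this interval too treats dependent probes as independent. Slide or scan day is a candidate cause. The sitosterol T3 array run among the mercury slides, eel 47, stood at a median position of 0.187 between the T3 arrays of the mercury experiment, at 0, and the other sitosterol T3 arrays, at 1, while those 5 arrays stood at 0.509 to 1.89. It rests on 1 array, and an effect of ethanol or of the aquarium stays open beside it.

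For oestrogen receptor alpha in sitosterol eels, the row of the array stays open: on 3 mercury slides with 1 treatment per row the row difference was -0.226 of the sitosterol difference (SE 0.369), with log2 row differences of -0.88 to 0.38 on the single slides. An oestrogenic response may be another reading. The mean number of vitellogenin probes above background per array was 0.167 higher in sitosterol eels (95% bootstrap interval -0.167 to 0.556, 2-sided permutation p = 0.679), with any above background in 3 of 18 sitosterol and 2 of 18 ethanol eels. The bound set for this test was wrong, because probes at the floor cannot show a small rise, so it stays open.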

How the results depend on the processing

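Averaging of identical sequences, leaving out slide 10 or the slide 9 array, muc2 as a covariate and, for lists, normexp, the deposited table and slide with row were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Of the counts under alternatives, 40 moved by more than 1.5 times. Where no cause is given, the cause was not tested.

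For sitosterol, limma's 0 became 160 at T2 with no filter on dim probes (158 higher and 2 lower), and 3 at T3 and 3 averaged over times with the slide as a block. It became 1 at T3 and 1 averaged over times with slide and row, and without the array on slide 9. It became 1 averaged over times with all 66 arrays, and 1 at T2 with array weights or identical sequences averaged.

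For mercury averaged over times, 252 became 388 with normexp, 121 with no filter, 462 with only probes above background on every array, 137 with the slide as a block, 0 with slide and row (1938 at an unadjusted p under 0.05), 410 with all 66 arrays, 458 with array weights and 442 with muc2. At T1, 388 became 155 with no filter, 659 with the strict filter, 65 with the slide (57 higher and 8 lower), 0 with slide and row (2107 unadjusted), 0 with only the 2 groups (5798 unadjusted), 1022 with array weights and 146 without slide 10 (84 and 62). At T2, 0 became 2 with normexp. At T3, 7 became 0 with slide and row (2305 unadjusted), 2 with only the 2 groups, and 31 with array weights (17 and 14), and was 8 without slide 10 (1 and 7). Between times 0 became 1 with array weights and 3 with muc2. At an unadjusted p under 0.05, 2077 of 41549 probes would be expected by chance in a mercury contrast.

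For ethanol against water eels 246 became 81 with normexp (61.7% higher, against 88.6%), 1589 with the deposited table (43.9% higher), 30 with the strict filter and 468 with the slide as a random block. The random block fit used an estimated within-slide correlation of -0.0557. The 2 controls shared no slide, so a negative value lowers the error of this comparison. The rise to 468 therefore does not show a difference that is stronger once slide is allowed for. Slide with row could not be fitted there. Of 49 list calls 0 held with an estimated correlation and 26 were made with slide and row. Of 32 calls of named genes 23 held with normexp, under which 14 differences shrank by more than 1.5 times. With the slide 15 held. With slide and row 0 held, and 25 of 26 differences kept their direction while 15 of 26 shrank by more than 1.5 times. With other arrays in the fit, which has fewer samples at single times, 17 held.

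Directions reversed in sitosterol eels for CYP1A1 (-0.023 with normexp, -0.019 with array weights), CYP1A9 (0.12 with normexp, 0.022 with T3-titled arrays as T2), CYP1A (-0.080) and heme oxygenase 1 (0.059), the last pair with slide and row. In mercury eels they reversed for the adenosylmethionine entry at T2 (-0.025 with normexp) and oestrogen receptor alpha (-6.2e-04 with normexp, -0.16 with muc2). With slide and row they reversed for the 3-oxo-5-alpha-steroid entry (0.79), the Pi-class transferase (-0.22), a glutamine synthetase contig (1.27) and smooth muscle actin (0.0092). Between controls they reversed for CYP1A9 (0.58 with the deposited table, 0.017 with array weights, 0.015 with muc2) and heme oxygenase 1 (-0.76 with the deposited table). Lists reversed with slide and row were ribosome at T2 (adjusted p = 0.12) and averaged (3.0e-11), and stellate at T3 (0.92) and averaged (0.68), in mercury eels. With the deposited table ribosome (0.94) and proteasome (0.69) reversed between controls.

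Leaving out 1 array gave 0 to 1 for sitosterol at T1, T2, T3 and averaged, and 0 between times. It gave 1 at T1 without sitosterol T3 eel 24, 1 at T2 without sitosterol T2 eel 62 or ethanol T3 eel 75, and 1 at T3 and averaged without sitosterol T3 eel 47. Ethanol against water gave 199 to 291. Mercury T1 gave 61 to 987: without water T1 eels 1, 25, 26, 49 and 50 it was 77, 61, 126, 138 and 980 (448 higher and 532 lower), without mercury T1 eels 3, 4, 27, 28 and 52 it was 987, 86, 70, 110 and 96, without mercury T2 eel 11 754 and without mercury T3 eel 73 257. Mercury averaged gave 104 to 480: water T1 eels 1 and 26 gave 142 and 163, mercury T1 eels 3, 27 and 52 gave 480, 165 and 137, water T2 eels 9, 33, 34 and 57 gave 131, 160, 404 and 147, mercury T2 eels 11 and 12 gave 149 and 135, water T3 eels 17, 18 and 41 gave 150, 166 and 394, and mercury T3 eels 19, 20, 44 and 66 gave 473, 134, 146 and 104. Mercury T2 gave 0 to 92 (89 and 92 without mercury T2 eels 35 and 58, 1 without water T3 eel 41), T3 gave 7 to 13 (13 without mercury T2 eel 11) and between times 0 to 2 (2 without that eel).

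The median of all probes moved to -0.14 with normexp and -0.21 with no filter at mercury T2, and to 0.19 at sitosterol T2 with no filter. Signal over background limits the probes that can be tested, at 45.6% to 69.3% of each array.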
